A study of Mus musculus with 12 samples.

How the data were processed

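Bulk RNA sequencing was done on mouse CD8+ T cells grown from whole spleens of 6 T cell receptor transgenic mice, 3 mice in each of 2 experiments. Per the labels' protocols, spleen cells were stimulated for 24 hours with 250 nM SIINFEKL peptide (OT-1 mice) or 1 uM gp100 peptide (pmel-1 mice), then expanded for 6 days with or without 5 mM dichloroacetate (DCA), and sorted for CD8 on day 7. DCA is an inhibitor of the pyruvate dehydrogenase kinases. Amplified cDNA was made with a SmartSeq kit over 15 cycles. Cells of each mouse went into both arms, so the 12 libraries form 6 pairs. The labels name 2 technical batches, and the library names in the count table separate the experiments in the same way. Strain, batch and experiment therefore coincide.

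The authors deposited a table of whole-number read counts per gene for 56748 genes and 12 libraries, with no normalization. Per the submitters' processing notes, fastp 0.23.2, STAR 2.7.10a, edgeR 3.36.0 and the genome build GRCm39 were used. The read counter, the annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes could not be separated. The authors also deposited a table of their own comparison of DCA with untreated cells, with log2 fold changes and log2 CPM, per the file headers. That table also holds p-values and false discovery rates, per the file headers, and a gene length column, deposited by the authors, that was not used here. Of its 15067 genes, 1588 had a false discovery rate under 0.05. All value columns were matched to a library or to the authors' comparison (0 unmapped columns). Symbols came from the authors' deposited table for 15067 genes and from a GRCm38 gene list for 37502 more; 469 tested genes had no symbol. That reference was used for symbols, older gene names, and transcript GC content and length, and for no coordinates.

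Total counts per library were between 28039700 and 41051100 (rounded to 6 digits). No library matched another within sampling noise: the chi-square per degree of freedom between replicates of a group was 11.5 to 33.2. The libraries carry no molecular identifiers, so counting intervals and limits for genes at 0 (3 counts) cover counting error only. The pairing of libraries comes from the design, since the same mouse gave both arms. Libraries of the same mouse had correlations of 0.0443 to 0.0834 between their deviations from the group means, against -0.0689 to -0.00438 for libraries of different mice.

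Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr by the 4 groups, Benjamini-Hochberg adjustment, threshold 0.05) over 15688 genes. DCA was compared with untreated cells over both experiments with a term for experiment. The DCA effect within each experiment, the difference of the effects, and experiment 2 against experiment 1 in untreated cells were contrasts of 1 fit with 4 group means. Standard errors (SE) of log2 fold changes were the absolute log2 fold change divided by the square root of the F statistic. Adjusted p-values for single genes are from this edgeR test unless another tool is named, with 3 libraries per group.

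There were 26 gene lists fixed before the data were examined, together with the comparisons, the rule for genes to name and the settings to vary. They held 602 different genes, of which 11 were matched through a synonym and 0 stayed unmatched. The 24 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The adjusted p of a list is camera's unless stated otherwise. Camera asks whether a list moved against the other genes; fry asks whether its members moved, on balance, one way. Libraries are described with CPM per total count, and single genes with CPM after TMM scaling. Library measures were compared between the arms of the 6 mice with an exact two-sided test of all sign changes.

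The rule named the 10 largest rises and 10 largest falls over both experiments among called genes with a mean log2 CPM of at least 3, the same sign in all 6 mice and an established symbol. It also named 22 fixed genes, up to 2 rising and 2 falling members of each list by adjusted p, up to 5 genes per direction for the difference between experiments and for the untreated cells, and T cell receptor segments of both transgenes. Of the fixed genes, Pdk4 had 4 counts in total and was not tested.

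Alternatives were RLE size factors, limma-voom, DESeq2 1.42.0, no filter on low counts, a filter at 5 CPM in 3 libraries, mitochondrial genes left out, an absolute log2 fold change of at least 1, a term per mouse (replicate block), no experiment term, fewer libraries in the fit, a prior count of 0.5 for lists, and each library left out in turn. A minimum fold of 1.1, removal of a GC trend and cyclic loess normalization were added after seeing the data, as were 9 further gene lists. Single genes were tested with limma on log2 CPM after GC removal and cyclic loess, and the same limma test with TMM scaling alone was added to tell the scaling from the test. Cyclic loess removes trends of fold change with expression level.

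The tests were run on simulated counts with 200 of 15688 genes changed, 100 by 0.5 and 100 by 1 on the log2 scale. For DCA over both experiments, 26 and 58 of each 100 were recovered, and 3 of 87 calls were genes that had not been changed. The recovered numbers were 14 and 49 for experiment 1, 17 and 57 for experiment 2, 1 and 25 for the difference between experiments, and 12 and 36 for the untreated cells. In these 4 simulations 1 of 64, 5 of 79, 2 of 28 and 6 of 54 calls were false. The data gave 2638 calls over both experiments, 8131 in the untreated cells and 52 for the difference, against 200 genes changed here. The simulations also had no effect shared by the libraries of a mouse. These recovered shares therefore need not hold in the data. A simulated list of 30 genes changed by 0.5 over both experiments had an adjusted p of 1.74e-15 (0.000133 with an estimated correlation), and 0 of 23 random lists were called. Simulated genes were drawn independently, so this could not test false calls of lists whose genes move together. In the data the estimated correlation over both experiments was 0.624 for the MYC and ribosome biogenesis list.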

Results

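Gene expression was measured by bulk RNA sequencing in CD8+ T cells that had been expanded in culture with IL-2, with or without 5 mM DCA, an inhibitor of the kinases that switch off pyruvate dehydrogenase. Spleen cells of T cell receptor transgenic mice were stimulated with their peptide for 24 hours, expanded for 6 more days and sorted on day 7. Each of 2 experiments had 3 mice, and each mouse gave 1 untreated and 1 DCA library, so each of the 4 groups had 3 libraries. The title of the series names the purpose as limiting metabolic stress in T cells made for cancer therapy by changing how they use glucose. Library totals ran from 28039700 to 41051100 counts (rounded to 6 digits). Between 18382 and 19551 genes were detected per library in experiment 1 and between 23635 and 26571 in experiment 2. Transcripts of Cd8a, the CD8 alpha chain, made up 274 to 738 CPM (counts scaled to the library total) in all 12 libraries, and Cd4 at most 0.638 CPM.

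The first principal component of log2 CPM took 54.3% of the variance and separated the experiments. The second took 10.2% and separated DCA from untreated libraries within each experiment. The share of counts taken by the 10 most counted genes was lower with DCA in 6 of 6 mice, by -0.416 ± 0.232 percentage points (mean ± SD, n = 6, exact two-sided p = 0.03125, the smallest that 6 pairs allow; adjusted over 6 library measures 0.0938). The TMM factor was higher with DCA in 6 of 6 mice, by 0.0658 ± 0.0252 (n = 6, exact two-sided p = 0.03125, adjusted 0.0938). Ribosomal protein genes took 0.405 ± 0.278 percentage points more of the counts with DCA, higher in 5 of 6 mice (exact two-sided p = 0.0625, adjusted 0.125). Over all 6 mice, genes detected (-818 with DCA), mitochondrial share (0.0841 points) and total count (higher in 2 of 6 mice) did not pass the exact test. The exact p was 0.156, 0.594 and 0.219 (adjusted 0.234, 0.594 and 0.263). This test pooled the experiments. The mitochondrial share was 1.01% to 1.14% untreated and 1.32% to 1.58% with DCA in experiment 1. In experiment 2 it was 2.27% to 2.85% and 2.11% to 2.40%. Genes detected were 18382 to 19551 untreated and 18747 to 19322 with DCA in experiment 1. In experiment 2 they were 24831 to 26571 and 23635 to 24326.

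**Figure D1:**
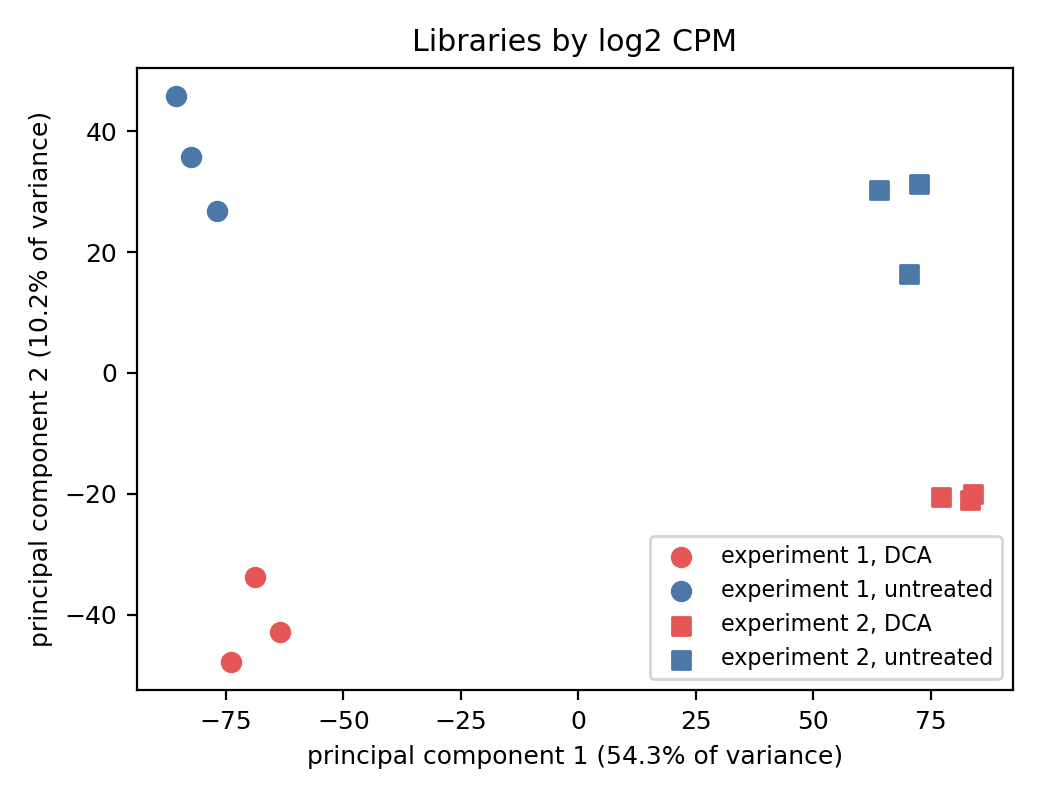
Principal components of log2 CPM, with 1 point per library (12 libraries, 3 per group), the first component (54.3% of the variance) on the x axis and the second (10.2%) on the y axis, both in component units. Experiment 1 lies at negative and experiment 2 at positive values of the first component, and in both experiments the DCA libraries lie below the untreated ones on the second.

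T cell receptor transcripts differed between the experiments. In experiment 1 the titles name Pmel-1 cells while the strain and genotype tags name OT-1, and both name Pmel-1 in experiment 2. Trbv12-1, a beta segment of the V beta 5 family that the OT-1 receptor uses, was at 169 to 214 CPM in the 6 libraries of experiment 1 and at 0.0688 to 0.550 CPM in experiment 2. Trbv14, the beta segment of the pmel-1 receptor, had 0 counts in all 6 libraries of experiment 1 and 1966 to 2876 CPM in experiment 2, at least 152857-fold higher against a limit of 3 counts over the group. Trbv12-2 was at 0.0709 to 0.592 CPM in experiment 1 and at a mean of 30.7 ± 7.24 CPM (SD, n = 6) in experiment 2. Of the alpha segments fixed for the same check, Trav14D-1, Trav14D-2 and the Trav7D segments were not matched by name and were not examined. The matched ones, of Trav14 and Trav7, stayed at or below 5.09 CPM in both experiments. Among them Trav7-3, Trav7-4 and Trav14D-3 were higher in each library of experiment 2 than in any of experiment 1. They had maxima of 0.0592, 0.710 and 0.198 CPM in experiment 1 and minima of 0.172, 0.810 and 0.344 CPM in experiment 2. Groups were kept as the labels give them.

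**Figure D2:**
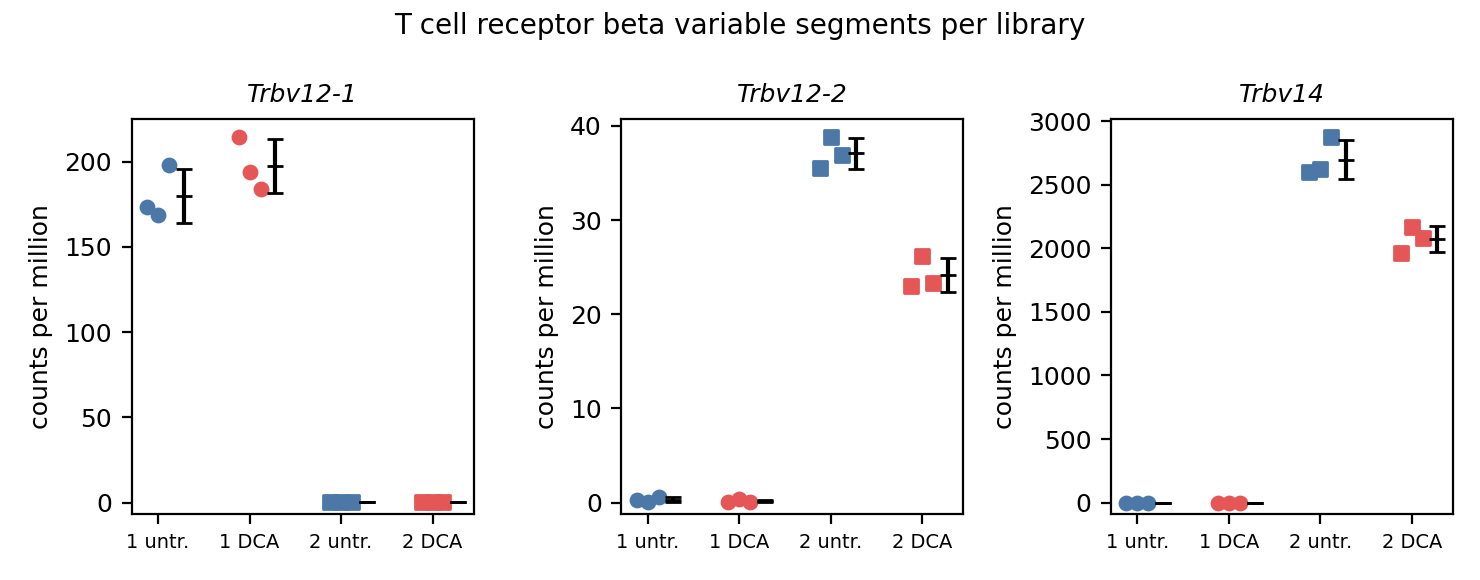
CPM, scaled to total counts (y axes), of the T cell receptor beta segments Trbv12-1, Trbv12-2 and Trbv14 in the untreated and DCA libraries of experiments 1 and 2 (x axes), with 1 point per library and the mean ± SD of the 3 libraries at the right of each group. Trbv12-1 lies between 169 and 214 CPM in experiment 1 and at or below 0.550 CPM in experiment 2, and Trbv14 lies at 0 in experiment 1 and between 1966 and 2876 CPM in experiment 2.

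The main question was how expansion with DCA changed the T cells over both experiments. Serpine2 (ENSMUSG00000026249), which encodes a secreted serine protease inhibitor, rose most among called genes with a mean log2 CPM of at least 3, from 60.6 ± 26.7 to 373 ± 141 CPM (SD, n = 6 libraries per arm; log2 fold change 2.63, SE 0.33, adjusted p = 0.000198). Slamf6, a receptor of the SLAM family found on stem-like T cells, rose from 8.55 ± 6.09 to 37.0 ± 24.3 CPM (2.13, SE 0.18, adjusted p = 1.9e-05). Zmat3, a p53 target gene, rose by 1.88 (SE 0.16, adjusted p = 1.66e-05) and the transcription factor gene Tcf7 by 1.27 (SE 0.20, adjusted p = 0.000946). Gzma, the gene of the cytotoxic protease granzyme A, fell by 1.25 (SE 0.12, adjusted p = 4.4e-05) and Fasl, the ligand of the death receptor Fas, fell by 0.65 (SE 0.06, adjusted p = 3.17e-05). The mitotic kinase gene Plk1 fell by 0.66 (SE 0.08, adjusted p = 0.000262).

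Other genes with the largest rises under the naming rule, which asked for a mean log2 CPM of at least 3, were Tex15 (log2 fold change 2.19), Cox6b2 (2.13), the immune inhibitory ligand gene Cd200 (2.13), Nebl (2.12), the tetraspanin gene Cd81 (1.92), Tmem141 (1.82) and Armcx1 (1.73). The largest falls under the same rule were those of the interferon-inducible GTPase gene Iigp1 (-1.41), Tmem176a (-1.35), Fgl2 (-1.32, SE 0.09), Gzma, Spp1 (-1.08, the gene of osteopontin), Tmem176b (-1.07), the interferon-inducible genes Ifi208 (-1.05) and Rtp4 (-0.998), Clnk (-1.03) and Ly6c2 (-1.01). Each of these changed in the same direction in 6 of 6 mice and was called, both of which the rule required, with adjusted p between 2.84e-06 (Fgl2) and 0.0167 (Rtp4).

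For DCA against untreated over both experiments, 2638 of 15688 genes were called, 1100 higher and 1538 lower with DCA, and 4700 had an unadjusted p under 0.05. Of the calls, 403 had an absolute log2 fold change of at least 1, with 339 higher and 64 lower. After cyclic loess normalization, tested with limma, 1231 genes were called higher and 1036 lower, with 1797 calls shared. The same limma test with TMM scaling called 1217 higher and 1609 lower, so the larger number of lower calls depended on the scaling. Without the experiment term 46 genes were called.

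**Figure D3:**
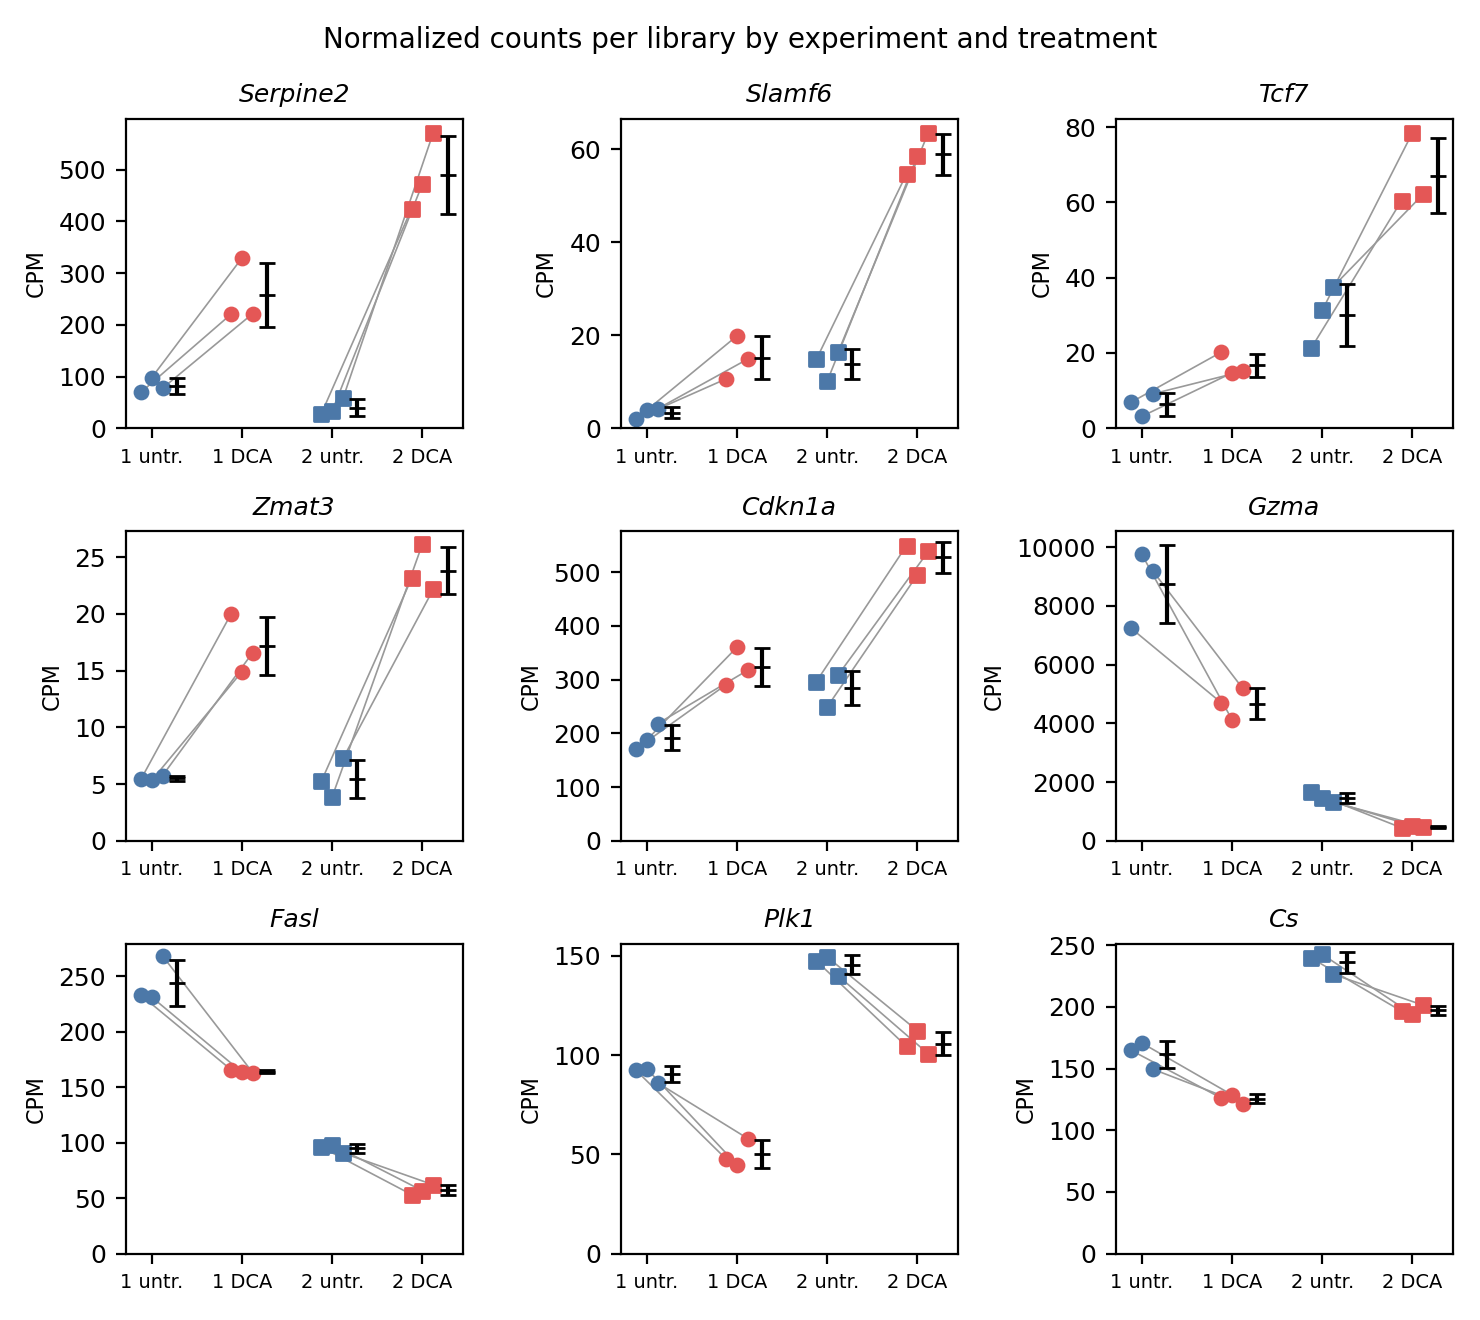
CPM after TMM scaling (y axes, from 0) of Serpine2, Slamf6, Tcf7, Zmat3, Cdkn1a, Gzma, Fasl, Plk1 and Cs in the untreated and DCA libraries of experiments 1 and 2 (x axes), with 1 point per library, grey lines joining the libraries of a mouse, and the mean ± SD of the 3 libraries at the right of each group. Serpine2, Slamf6, Tcf7, Zmat3 and Cdkn1a were higher and Gzma, Fasl, Plk1 and Cs lower with DCA in 6 of 6 mice.

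Genes of the p53 pathway rose. Of 24 tested members of the list of p53 targets and apoptosis genes, 11 rose and 0 fell (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.55 (camera adjusted p = 5.42e-06; adjusted p = 0.0252 with an estimated correlation). Cdkn1a, the gene of the cell cycle inhibitor p21, rose from 238 ± 56.5 to 425 ± 116 CPM (0.82, SE 0.08), along with Zmat3. Bax, a member of the list, was lower in CPM with DCA in each mouse of experiment 1 and higher in each mouse of experiment 2. With a term per mouse the list's adjusted p with an estimated correlation was 0.203, and without exp1_DCA replicate 2 it was 0.0655.

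Proliferation genes fell. Of 36 tested, 0 rose and 24 fell (0 and 26 adjusted over the list alone), with a median of -0.24 (adjusted p = 9.42e-10; 0.0148 with an estimated correlation). Plk1 and Cdc20 (-0.60), both needed for mitosis, had the smallest adjusted p. After cyclic loess normalization the median was -0.10, still negative, with an adjusted p of 0.00214 by camera and 0.287 with an estimated correlation. Leaving out exp2_untreated replicate 1 or 3 or exp2_DCA replicate 1, 2 or 3 gave an estimated-correlation adjusted p of 0.0841, 0.109, 0.0928, 0.0983 and 0.103.

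Several lists of mitochondrial metabolism were lower with TMM scaling. Genes of the tricarboxylic acid cycle fell in 12 of 20 cases, with 0 rises (15 and 0 adjusted over the list alone; median -0.23, adjusted p = 3.06e-06), among them citrate synthase, Cs (-0.31, SE 0.05). Of the nuclear-encoded respiratory chain, 29 of 52 members fell and 1 rose (34 and 2 adjusted over the list alone; median -0.18, adjusted p = 2.78e-09), with Atp5a1, a subunit of ATP synthase, at -0.44 and cytochrome c, Cycs, at -0.39. The pyruvate dehydrogenase list had 7 falls and 0 rises of 15 (8 and 1 adjusted over the list alone; median -0.17, adjusted p = 0.00937), including Mpc1, a subunit of the mitochondrial pyruvate carrier (-0.28, SE 0.07, adjusted p = 0.00863), and Pdhx (-0.29). With an estimated correlation these lists had adjusted p = 0.218, 0.255 and 0.255. After cyclic loess normalization the respiratory chain (adjusted p = 0.280), the pyruvate dehydrogenase list (0.102) and Mpc1 (limma adjusted p = 0.0608) were no longer called, with values of -0.05 (21 of 52 members above 0), -0.08 and -0.21. The tricarboxylic acid cycle was still called by camera (0.0171), with a median of -0.10. Mitochondrially encoded genes went both ways, with 3 rises and 1 fall of 12 (the same adjusted over the list alone; median 0.22, adjusted p = 0.130; 0.618 with an estimated correlation). By camera with a preset correlation the list was called without exp2_untreated replicate 1 (0.0252). Among them, mt-Co1 rose by 0.57 and mt-Nd1 was at -0.34, a call lost under cyclic loess (limma adjusted p = 0.338). Reads of such genes can be shared with near-identical nuclear copies, so their values are uncertain.

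Glycolysis genes were not called as a list: 5 of 23 rose and 3 fell (5 and 5 adjusted over the list alone), with a median of -0.02, a mean of 0.16 and a test direction upward (adjusted p = 0.494). After cyclic loess normalization the sign of the median turned (0.13) and the list was called upward (adjusted p = 0.00273; 0.440 with an estimated correlation). Ldhb (0.88) and Aldoc (0.77) rose. Ldha, the main lactate dehydrogenase gene of T cells, was at -0.17 (SE 0.05, adjusted p = 0.0168), 0.0525 with a term per mouse, 0.0597 with a stricter filter, and at 0.0062 under cyclic loess, where its sign turned. Eno1 was at -0.25, a call lost under cyclic loess (limma adjusted p = 0.489). Among the kinase genes targeted by DCA, Pdk1 was at 0.26 (SE 0.10, adjusted p = 0.0918), called under cyclic loess (limma adjusted p = 0.0347), with no filter (0.0233) and with a stricter one (0.0432). Pdk2 was at 0.63 (SE 0.51, adjusted p = 0.463; 0.0257 without exp1_untreated replicate 2 and 0.0321 by limma-voom) and Pdk3 at -0.17 (SE 0.07, adjusted p = 0.130; 0.0173 without exp1_DCA replicate 2). Pdha1 (-0.15, adjusted p = 0.138), the glucose transporter gene Slc2a1 (0.10, adjusted p = 0.424), Hk2 (-0.09, adjusted p = 0.385), the lactate transporter gene Slc16a3 (-0.06, adjusted p = 0.737) and the ATP citrate lyase gene Acly (-0.05, adjusted p = 0.694) were not called. Acss2, which makes acetyl-CoA from acetate, was at 0.44 (SE 0.16, adjusted p = 0.0648), and was called without exp1_DCA replicate 3 (0.0156) or exp2_DCA replicate 3 (0.0485), with no filter (0.0102), with a stricter filter (0.0301) and by DESeq2 (0.0286).

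Genes of naive, stem and central memory T cells rose more often than they fell, 10 against 2 of 24 (the same adjusted over the list alone), with a median of 0.26 (adjusted p = 0.00178; 0.222 with an estimated correlation). Slamf6, Id3 (0.88) and Tcf7 rose, as did the lymph node homing receptor gene Ccr7 (0.62, SE 0.11, adjusted p = 0.00159). Ly6c2 and Eomes (-0.91) fell. Il7r was at -0.05 (adjusted p = 0.867). The effector and cytotoxic list had 4 rises and 7 falls of 32 (5 and 8 adjusted over the list alone; median -0.14, adjusted p = 0.188; 0.000958 by fry, which called it lower). Beside Gzma and Fasl, Prdm1, the gene of Blimp-1, rose by 0.98, and Zeb2 rose from a low level (0.209 to 1.46 CPM, log2 fold change 2.77, SE 0.65). Gzmb was at -0.13 (adjusted p = 0.265) at 9218 CPM untreated. Ifng was near the floor, at 0.810 against 0.187 CPM (-2.18, SE 0.68, adjusted p = 0.0394; 0.0730 with a term per mouse and 0.0513 by limma-voom), and kept its call in only 3 of the 12 fits that left out 1 library. Inhibitory receptor and exhaustion genes had 4 rises and 2 falls of 21 (6 and 3 adjusted over the list alone; median 0.03, mean 0.34, adjusted p = 0.188). Cd200 and Btla (1.85) rose and the ectonucleotidase gene Entpd1 fell by 0.88. Pdcd1, the gene of PD-1, was at 0.48 (adjusted p = 0.128; 0.0233 without exp1_DCA replicate 3 and 0.00417 with no filter), Havcr2 at 0.01 (adjusted p = 0.981), and Tox at 0.84 (adjusted p = 0.0857; 0.0310 by limma-voom, 0.0372 by DESeq2, 0.00185 with no filter, 0.0480 with a stricter one, 0.0158 without exp1_untreated replicate 3 and 0.0191 without exp1_DCA replicate 1). Cd8a was at -0.19 (adjusted p = 0.0985; 0.0200 without exp1_untreated replicate 2 and 0.0287 without exp1_DCA replicate 3).

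Hypoxia-induced genes had 8 rises and 2 falls of 24 (13 and 3 adjusted over the list alone; median 0.25, adjusted p = 0.000361; 0.293 with an estimated correlation; 0.0236 by fry, and 0.0987 by fry with a term per mouse), with Kdm3a at 0.59 and Ankrd37 at 0.97, while Hif1a, the hypoxia-inducible factor gene, fell by 0.50. The MYC and ribosome biogenesis list had 9 falls and 0 rises of 27 (13 and 0 adjusted over the list alone; median -0.33, adjusted p = 7.26e-05; 0.511 with an estimated correlation; 0.0589 by fry; median -0.21 under cyclic loess), led by Rrp9 (-0.66) and Mybbp1a (-0.50). Interferon response genes fell in 10 of 34 cases with 0 rises (the same adjusted over the list alone; median -0.23, adjusted p = 0.00178; 0.268 with an estimated correlation), including the immunoproteasome gene Psmb8 (-0.42) and Gbp4 (-0.53). The median of this list was -0.44 in experiment 1 and -0.06 in experiment 2, where it was not called (camera adjusted p = 0.106). The difference between experiments was not called either (0.0901). Of 24 genes of cholesterol synthesis and uptake, 7 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.16, adjusted p = 0.000315; 0.268 with an estimated correlation; 0.0561 with a median of -0.07 under cyclic loess), among them squalene epoxidase, Sqle (-0.50), and Fdps (-0.55).

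The remaining lists of pathways were not called. Fatty acid oxidation had 2 rises and 8 falls of 24 (the same adjusted over the list alone; median -0.03, adjusted p = 0.262; 0.0326 by fry, and 0.0987 by fry with a term per mouse), with Eci2 at 0.35 and Acsl5 at -0.38. Fatty acid synthesis had 3 rises and 3 falls of 16 (4 and 3 adjusted over the list alone; median -0.08, mean 0.08, test downward, adjusted p = 0.922, the median turning to 0.02 under cyclic loess), with Scd2 at 0.42 and Elovl6 at -0.32. Acetyl-CoA supply and histone acetylation had 3 rises and 3 falls of 23 (5 and 6 adjusted over the list alone; median -0.13, mean 0.01, test downward, adjusted p = 0.721), with the histone acetyltransferase gene Ep300 at 0.49 and Hdac7 at 0.43. The integrated stress response list had 1 rise and 4 falls of 29 (3 and 5 adjusted over the list alone; median -0.00, mean 0.09, test upward, adjusted p = 0.811). Oxidative stress defence had 2 rises and 4 falls of 28 (2 and 5 adjusted over the list alone; median -0.11, mean 0.02, test downward, adjusted p = 0.396, the median turning to 0.01 under cyclic loess), with Prdx2 at 0.41. Autophagy and lysosome genes had 3 rises and 2 falls of 26 (the same adjusted over the list alone; median 0.06, adjusted p = 0.380), with the protease gene Ctsl at 2.09. Immediate early genes had 1 rise, of Atf3 (0.74), and 0 falls of 16 (the same adjusted over the list alone; median 0.02, adjusted p = 0.417).

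Markers of other cells that a CD8 sort could hold were at levels from 0 counts (C1qa) to a group mean of 496 CPM (Ighm). Some rose with DCA. Of 9 tested myeloid and dendritic cell markers, 3 rose and 0 fell (the same adjusted over the list alone; median 0.81, adjusted p = 0.0140; 0.255 with an estimated correlation; 0.0710 with a stricter filter and 0.0576 without exp1_DCA replicate 2). They were H2-Eb1 (2.42, from 0.714 to 3.83 CPM), Tyrobp (2.06, at 0.998 CPM untreated; adjusted p = 0.0120, 0.0636 with a term per mouse and 0.0588 by limma after cyclic loess) and H2-Ab1 (0.47, adjusted p = 0.0218), which was at group means of 138 to 351 CPM. Of the markers named, H2-Ab1, Lyz2, Csf1r, C1qa, Cd68, Fcgr3, Cd74, Ighm, Ms4a1 and Trgc1 were chosen after their values had been seen. Over the 12 libraries there were 14 counts of Lyz2, 6 of Csf1r and 0 of C1qa. There were 5050 of Cd68 (0.58, adjusted p = 0.143), 1725 of Fcgr3 (0.30, adjusted p = 0.621) and 1418 of Cd74 (1.04, adjusted p = 0.205). Among 3 tested B cell markers, Cd79b (0.75) and Ighd (1.08) rose and 0 fell (the same adjusted over the list alone; median 0.75, no list test with under 5 members). Ighm, at group means of 298 to 496 CPM, was not called (0.15, adjusted p = 0.325) and Ms4a1 had 2 counts in total. Natural killer and gamma delta cell markers had 1 rise (Tyrobp) and 2 falls (Eomes, and Trdc at -0.49) of 10 (the same adjusted over the list alone; median -0.08, mean 0.02, adjusted p = 0.380). Trgc1, at group means of 292 to 443 CPM, was not called (0.11, adjusted p = 0.817). Of 5 CD4 T cell markers and 3 erythroid and platelet markers, 0 rose and 0 fell (the same adjusted over each list alone; medians 0.11 and 0.29, the CD4 median turning to -0.04 under cyclic loess and the erythroid mean at -0.15).

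**Figure D4:**
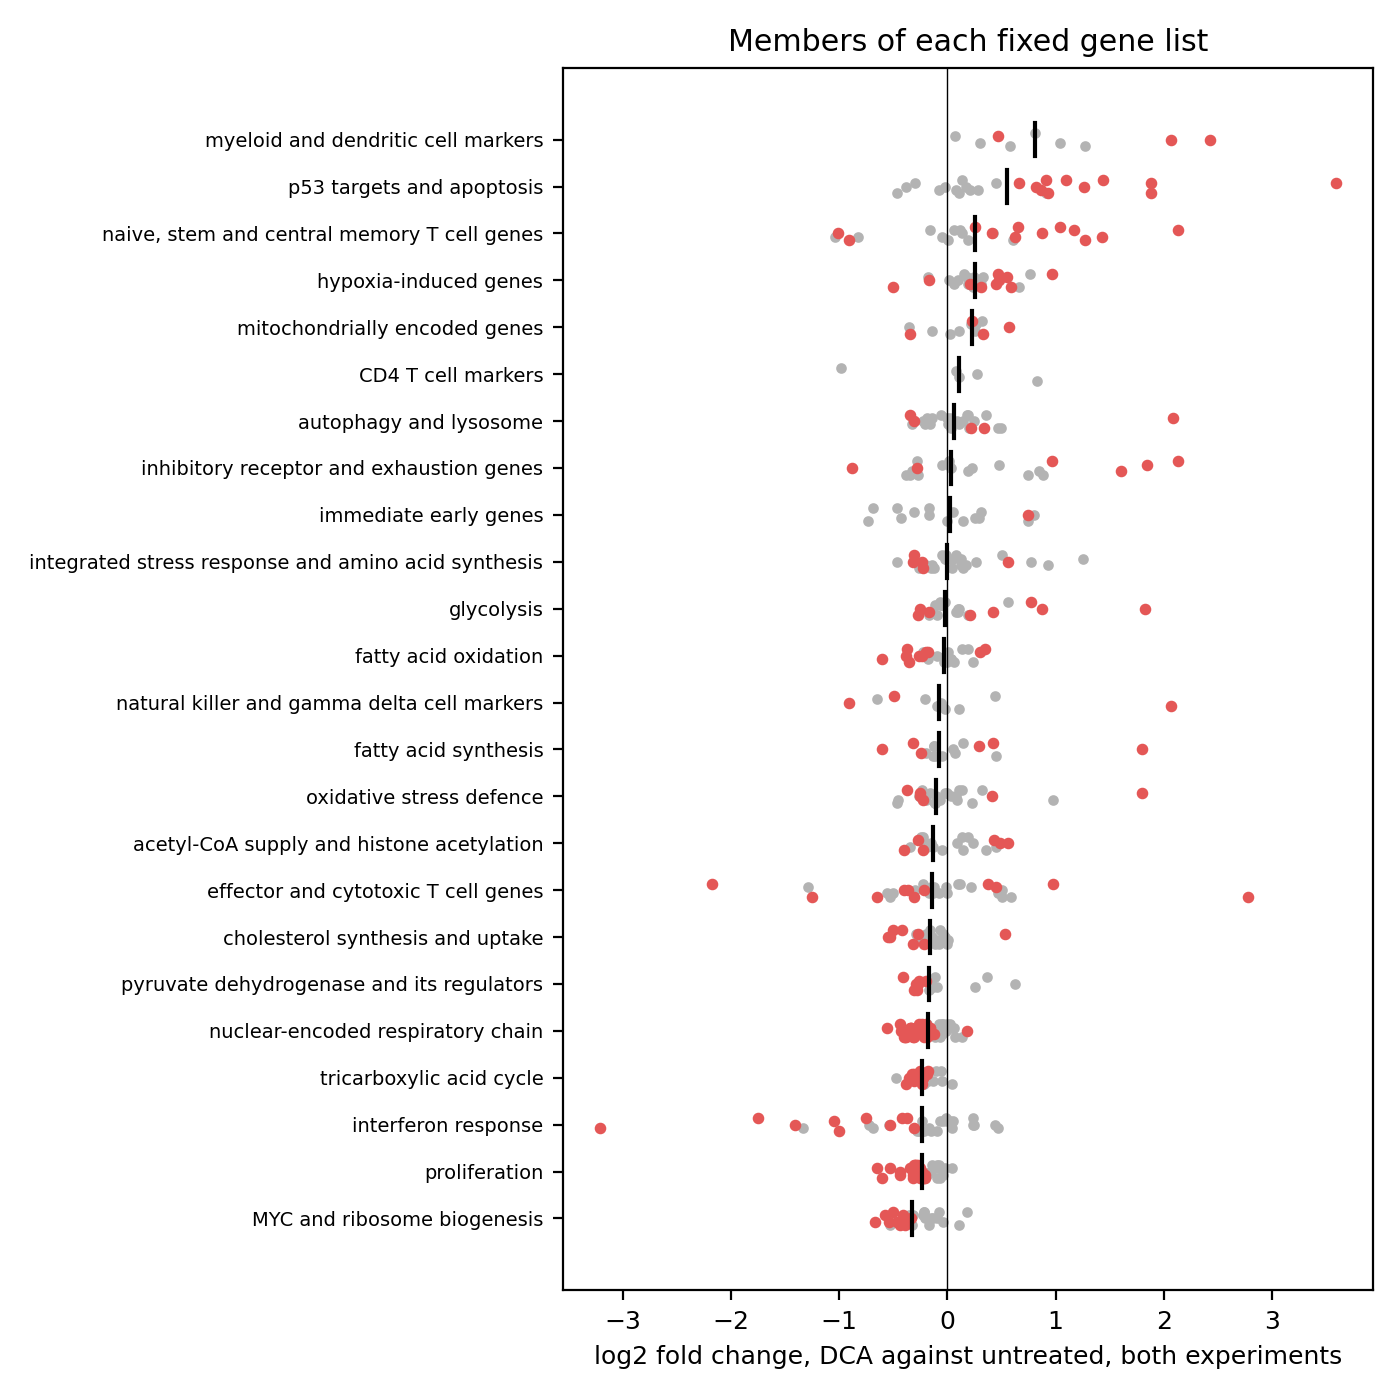
Log2 fold change of DCA against untreated cells over both experiments (x axis) for the tested members of the 24 lists with at least 5 of them (y axis), with 1 point per gene, called genes in red and a black bar at each list's median. Medians run from 0.81 (myeloid and dendritic cell markers) to -0.33 (MYC and ribosome biogenesis), and those of glycolysis, fatty acid synthesis, the integrated stress response, oxidative stress defence and CD4 markers turned sign under cyclic loess scaling.

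Within experiment 1, Slamf6 rose by 2.16 (SE 0.27), Serpine2 by 1.66 (SE 0.23) and Zmat3 by 1.64 (SE 0.21), and Gzma fell by 0.90 (SE 0.11) and Plk1 by 0.85 (SE 0.10), with n = 3 mice. Genes of MYC and ribosome biogenesis fell in 17 of 27 cases with 0 rises (21 and 0 adjusted over the list alone; median -0.52, adjusted p = 1.66e-08; 0.256 with an estimated correlation), Rrp9 by 1.05 (SE 0.13). Hypoxia-induced genes rose in 13 of 24 cases and fell in 2 (17 and 2 adjusted over the list alone; median 0.40, adjusted p = 1.1e-05; 0.256 with an estimated correlation). Pdk1 rose by 0.50 (SE 0.11, adjusted p = 0.00731). The p53 list had 9 rises and 2 falls of 24 (11 and 3 adjusted over the list alone; median 0.36, adjusted p = 0.00165; 0.0756 with an estimated correlation).

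For DCA against untreated in experiment 1, 2622 genes were called, 889 higher and 1733 lower, of which 1746 were also called over both experiments. Cyclic loess gave 1083 higher and 1041 lower, and the same limma test with TMM 938 and 1801. Of 24 lists, 13 were called (6 up, 7 down) and 0 with an estimated correlation (camera). The smallest such adjusted p was 0.0756, and fry called 15. Proliferation genes had 16 falls and 0 rises of 36 (20 and 0 adjusted over the list alone; median -0.22; adjusted p = 0.0756 with an estimated correlation and, by camera under cyclic loess, 0.0812 with a median of -0.05). Respiratory chain genes had 19 falls and 1 rise of 52 (21 and 2 adjusted over the list alone; median -0.16; 0.551 with an estimated correlation), and under cyclic loess their median turned to 0.04 with the call lost (0.198). Interferon response genes had 9 falls and 2 rises of 34 (15 and 2 adjusted over the list alone; median -0.44; 0.256 with an estimated correlation). Mitochondrially encoded genes had 5 rises and 0 falls of 12 (6 and 0 adjusted over the list alone; median 0.40, adjusted p = 0.00100; 0.256 with an estimated correlation). Naive and stem genes had 7 rises and 2 falls of 24 (12 and 3 adjusted over the list alone; median 0.32; 0.256 with an estimated correlation). The tricarboxylic acid cycle (8 falls of 20, 13 adjusted over the list alone), pyruvate dehydrogenase (5 falls and 1 rise of 15, 8 and 1 adjusted over the list alone) and cholesterol lists (6 falls of 24, 8 and 1 rise adjusted over the list alone) were called lower, with adjusted p = 0.256, 0.256 and 0.315 with an estimated correlation and 0.145, 0.198 and 0.177 by camera under cyclic loess, where their medians were -0.07, -0.12 and -0.07 (-0.25, -0.25 and -0.20 with TMM). Inhibitory receptor genes (6 rises and 1 fall of 21) and myeloid markers (2 rises of 9), with the same counts adjusted over each list alone, were called higher, with 0.279 and 0.256 with an estimated correlation and 0.0648 and 0.0779 under cyclic loess. The glycolysis list was called higher only under cyclic loess with a preset correlation (0.00269, and 0.440 with an estimated one).

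Within experiment 2, Serpine2 rose from 39.8 ± 15.9 to 489 ± 74.9 CPM (SD, n = 3; log2 fold change 3.62, SE 0.25), Zmat3 by 2.12 (SE 0.21) and Slamf6 by 2.10 (SE 0.25), while Gzma fell by 1.60 (SE 0.12) and Entpd1 by 1.14 (SE 0.12). The p53 list had 10 rises and 0 falls of 24 (13 and 0 adjusted over the list alone; median 0.83, adjusted p = 5.36e-09; 0.00391 with an estimated correlation). Proliferation genes fell in 11 of 36 cases with 0 rises (16 and 0 adjusted over the list alone; median -0.22, adjusted p = 5.56e-10), and the adjusted p with an estimated correlation was 0.0213 with TMM, 0.0597 with RLE and 0.327 after cyclic loess (median -0.14). The MYC and ribosome biogenesis list had 1 rise and 0 falls of 27 (the same adjusted over the list alone; median -0.02, turning to 0.01 under cyclic loess, adjusted p = 0.573).

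For DCA against untreated in experiment 2, 717 genes were called, 372 higher and 345 lower, and 616 of them were also called over both experiments. Cyclic loess gave 374 higher and 206 lower, the same limma test with TMM 398 and 353, and DESeq2 617 and 895. Leaving out exp2_untreated replicate 2, exp2_DCA replicate 1 or exp2_DCA replicate 2 gave 210, 260 and 271 calls. Which experiment had more calls depended on the fit: with each experiment fitted alone, experiment 1 had 1251 and experiment 2 had 1564. Of 24 lists, 6 were called (2 up, 4 down) and 2 with an estimated correlation, p53 and proliferation. Respiratory chain genes had 15 falls and 0 rises of 52 (37 and 0 adjusted over the list alone; median -0.21, and -0.12 under cyclic loess; adjusted p = 0.273 with an estimated correlation). The tricarboxylic acid cycle had 4 falls of 20 (8 adjusted over the list alone; median -0.19, and -0.11 under cyclic loess; 0.273 with an estimated correlation). Cholesterol genes had 1 fall of 24 (2 adjusted over the list alone; 0.476 with an estimated correlation and 0.0649 by camera under cyclic loess). Naive and stem genes had 5 rises and 2 falls of 24 (8 and 2 adjusted over the list alone; 0.438 with an estimated correlation). Hypoxia-induced genes (1 rise and 1 fall of 24) were called higher only under cyclic loess with a preset correlation (0.0171, and 0.578 with an estimated one). With TMM the interferon response list, with 3 falls and 0 rises of 34, was not called (median -0.06, camera adjusted p = 0.106). Mitochondrially encoded genes had 1 rise and 2 falls of 12 and were not called with TMM (median -0.03, camera adjusted p = 0.573). For both lists the counts were the same adjusted over the list alone.

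The effects of DCA in the 2 experiments, which share no library, went together. Across 15688 genes the log2 fold changes correlated with Pearson r = 0.265 and Spearman rho = 0.345, and with r = 0.528 across the 8122 genes with a mean log2 CPM of at least 3; genes are not independent replicates. Of the genes called higher in experiment 1 (889) and in experiment 2 (372), 192 were shared against 21.1 for independent lists (odds ratio 22.4, Fisher's exact p = 2.43e-142). Of those called lower (1733 and 345), 212 were shared against 38.1 (odds ratio 14.5, Fisher's exact p = 3.19e-116). The Fisher p-values and the numbers for independent lists treat genes as independent. Both sets of calls also came from 1 fit with a shared spread per gene, so these p-values do not measure agreement between mice. Of 411 genes called in both, 7 had opposite signs.

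**Figure D5:**
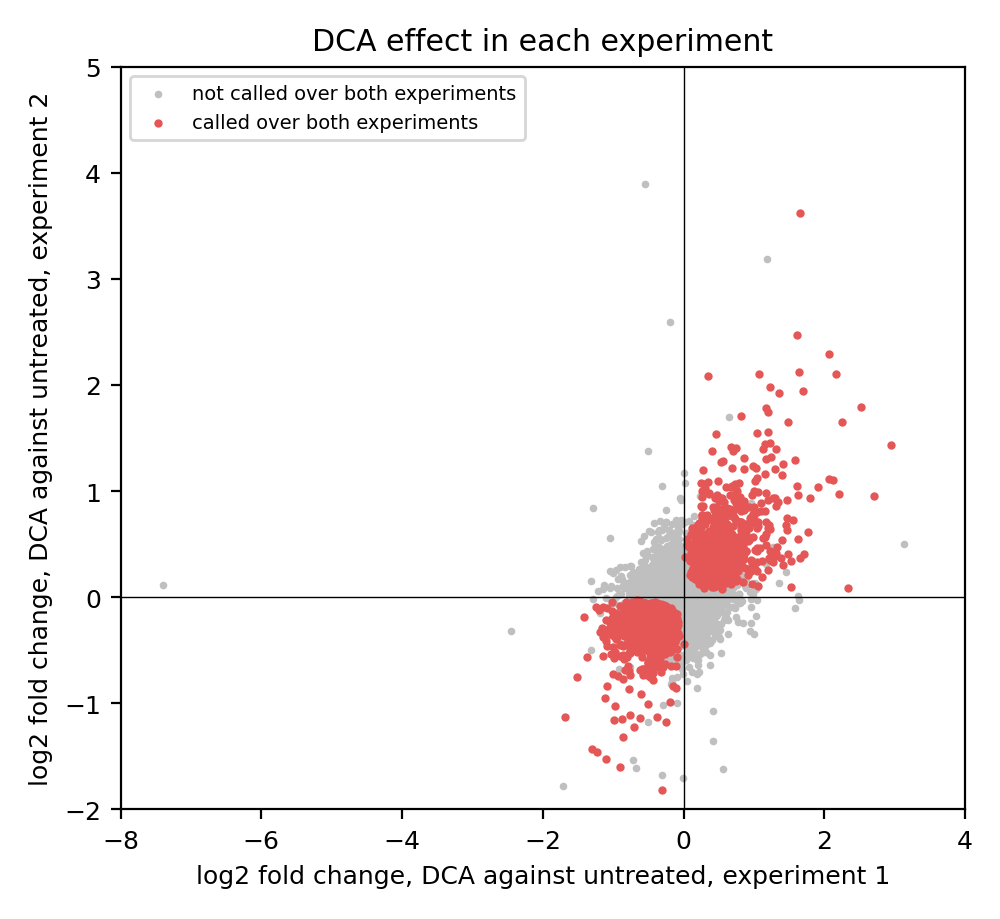
Log2 fold change of DCA against untreated cells in experiment 1 (x axis) and experiment 2 (y axis) for the 8122 genes with a mean log2 CPM of at least 3, with genes called over both experiments in red. The 2 effects correlated with r = 0.528 across these genes.

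A test of the difference itself asked where the DCA effect was not the same in both experiments. Lta, the gene of lymphotoxin alpha, fell by 0.47 in experiment 1 (SE 0.08) and rose by 0.61 in experiment 2 (SE 0.08), a difference of 1.08 (SE 0.11, adjusted p = 0.00119; 0.0180 with a term per mouse). For Serpine2 the difference was 1.96 (SE 0.33, adjusted p = 0.0223). The Serpine2 difference of log2 fold changes was not called without exp1_untreated replicate 2 (0.0575), exp1_DCA replicate 1 (0.0515), exp2_untreated replicate 1 or 2 (0.0998 and 0.101) or exp2_DCA replicate 1, 2 or 3 (0.0956, 0.0920 and 0.146). The pro-apoptotic gene Bax (difference 1.08, SE 0.13), the adhesion receptor gene Cd44 (1.11, SE 0.15) and Myc (0.88, SE 0.12) also had higher effects in experiment 2, and Gpat3, an enzyme gene of triglyceride synthesis, a lower one (-2.26, SE 0.34). The CPM of Bax, Cd44 and Myc was lower with DCA in each mouse of experiment 1 and higher in each mouse of experiment 2. For Pdk1 the difference was -0.47 (SE 0.15, adjusted p = 0.176).

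In all, 52 genes differed between the experiments, 44 with a higher effect in experiment 2 and 8 with a lower one, and 24 with a term per mouse (21 and 3). DESeq2 called 458, and leaving out 1 library gave between 1 and 217: 1 (Lta) without exp2_untreated replicate 1, exp2_untreated replicate 2 or exp2_DCA replicate 3, 2 without exp2_DCA replicate 2, 4 without exp2_DCA replicate 1, 7 without exp2_untreated replicate 3, 18, 11 and 217 without exp1_untreated replicates 1, 2 and 3, and 143 without exp1_DCA replicate 2. The number of genes that differ is therefore not fixed by these libraries. The MYC and ribosome biogenesis list had a higher effect in experiment 2 (median difference 0.43, adjusted p = 3.98e-08; 0.479 with an estimated correlation and 0.150 by fry), with 1 of 27 members called, and 14 adjusted over the list alone. The p53 list had a difference of 0.14 (adjusted p = 0.0901; 0.0222 by fry), with 4 of 24 members called and 5 adjusted over the list alone.

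The untreated cells of the 2 experiments differed in strain, peptide and batch together, and the size of that difference was set beside the effect of DCA. Glycolysis genes were higher in experiment 2, with 22 rises and 1 fall of 23 (the same adjusted over the list alone; median 1.38, adjusted p = 3.37e-09), including the pyruvate kinase gene Pkm (2.34, SE 0.08) and Ldha (1.84, SE 0.06). Of the nuclear-encoded respiratory chain, 46 of 52 genes were lower and 4 higher (46 and 5 adjusted over the list alone; median -1.03, adjusted p = 4.28e-15). Immediate early genes had 12 higher and 1 lower of 16 (median 1.49), mitochondrially encoded genes 11 higher and 0 lower of 12 (12 and 0 adjusted over the list alone; median 1.40), hypoxia-induced genes 17 and 1 of 24 (median 0.75), naive and stem genes 15 and 4 of 24 (median 0.72), autophagy genes 17 and 5 of 26 (median 0.72), fatty acid synthesis genes 12 and 0 of 16 (median 0.59), and natural killer and gamma delta markers 0 and 6 of 10 (median -1.84). Apart from the mitochondrially encoded genes, these counts were the same adjusted over each list alone. None of these 9 lists was called by camera with an estimated correlation (each adjusted p = 0.236), while fry called 21 of 24 lists in 1 direction or the other. Under cyclic loess the cholesterol, proliferation, fatty acid oxidation, tricarboxylic acid cycle and interferon lists were also called higher by camera, with 0.154 to 0.322 with an estimated correlation.

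Cotl1 (2.68), H2-Q7 (2.20) and H2-D1 (1.85) were also higher in experiment 2, and Mrpl42 (-2.82), Sub1 (-2.50), Calm2 (-2.41), Cnot9 (-2.35) and H3f3b (-1.98) lower, with adjusted p of at most 1.28e-11. H2-Q7 and H2-D1 belong to a family of near-identical class I genes, and H3f3b, Calm2 and Sub1 have related copies, so reads may have been split among copies. A total of 8131 genes were called, 4182 higher and 3949 lower, and 4492 by at least 1 on the log2 scale. The median over all genes was 0.11, and -0.01 after cyclic loess normalization, under which the glycolysis median was 2.38, the hypoxia median 1.35 and the respiratory chain median -0.34, and H3f3b moved to -0.77, Calm2 to -1.32, Sub1 to -1.30, and Ldha to 3.07.

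The authors' deposited table listed 1588 genes with a false discovery rate under 0.05, 772 higher and 816 lower. All 1588 were called here in the same direction over both experiments. A test here with a minimum fold of 1.1 called 1574 of the 15067 genes in the authors' deposited table, 1562 of them shared with it.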

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

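The test of the T cell receptor segments and the arm swaps of the agreement between experiments were chosen after the results had been seen.

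The DCA effect differed between the experiments for 52 genes by a test of the difference itself. Lta had the smallest adjusted p (difference of log2 fold changes 1.08, 0.00119), and was called in every alternative and without any 1 library. Cd44 (1.11), Bax (1.08), Snhg15 (0.96) and Myc (0.88) also had the higher effect in experiment 2, and Gpat3 (-2.26), mt-Rnr2 (-1.02), St6gal1 (-0.93), Appl2 (-0.84) and Dnajc15 (-0.67) the lower. The CPM of Cd44, Bax, Snhg15 and Myc was lower with DCA in each mouse of experiment 1 and higher in each mouse of experiment 2. Serpine2 rose in both experiments, by a larger estimate in experiment 2 (difference 1.96). The calls of Serpine2, Bax, Cd44, Snhg15, Myc, Gpat3, Dnajc15, St6gal1, Appl2 and mt-Rnr2 were each lost without some single libraries. Without exp2_untreated replicate 1 or 2 or exp2_DCA replicate 3, Lta was the 1 gene called. The Serpine2 difference of log2 fold changes was not called without any 1 of 7 libraries: adjusted p = 0.0575 without exp1_untreated replicate 2, 0.0515 without exp1_DCA replicate 1, 0.0998 and 0.101 without exp2_untreated replicates 1 and 2, and 0.0956, 0.0920 and 0.146 without exp2_DCA replicates 1, 2 and 3. Without exp2_untreated replicate 1, the adjusted p was 0.0690 for the Bax difference of log2 fold changes, and 0.0998 for the Myc difference of log2 fold changes. Without exp2_DCA replicate 3, the Cd44 difference of log2 fold changes had 0.0902 and the Snhg15 difference of log2 fold changes 0.110. The Gpat3 difference of log2 fold changes had 0.0717 without exp2_DCA replicate 2, and the Dnajc15 difference of log2 fold changes 0.0956 without exp2_DCA replicate 1. The largest adjusted p without 1 library was 0.126 for the St6gal1 difference of log2 fold changes, 0.131 for the Appl2 difference of log2 fold changes and 0.146 for the mt-Rnr2 difference of log2 fold changes, each without exp2_DCA replicate 3. With a term per mouse St6gal1 (0.0531) and Appl2 (0.104) were not called, and under cyclic loess the mt-Rnr2 difference of log2 fold changes was not (0.0732).

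By camera with a preset correlation, 5 gene lists had a different effect in the experiments. The median difference was 0.43 for MYC and ribosome biogenesis, -0.45 for mitochondrially encoded genes, -0.26 for hypoxia-induced genes, -0.22 for inhibitory receptor genes (not called under cyclic loess, 0.0685) and -0.10 for the nuclear-encoded respiratory chain (-0.19 under cyclic loess). With an estimated correlation 0 of 24 lists were called (smallest adjusted p = 0.479), and fry called 1, the p53 list (0.0222). With a term per mouse, 3 lists were called by camera, against a highest value of 5 among the other splits. There are 10 such splits, too few for a share under 0.05, and 3 of them gave a value as large as the real one. For single genes with a term per mouse the real value was 24 and the highest other was 1, again with 10 splits.

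The p53 list was higher with DCA over both experiments. Its mean change was above 0 in 6 of 6 mice (0.47 ± 0.15 in experiment 1 and 0.76 ± 0.17 in experiment 2, mean ± SD, n = 3 mice each, exact two-sided p = 0.03125 over the 6, the smallest possible). These are the same 6 mice that gave the list's call, so this is not separate support. Removal of a trend with GC content kept 96.8% of the list's median change (84.1% to 97.1% with 1 mouse left out), and cyclic loess kept 104% (89.8% to 116%), so neither trend was the whole cause. A response of p53 target genes to DCA is a candidate explanation. It stays a hypothesis, since the list's adjusted p with an estimated correlation was 0.203 with a term per mouse, and a change in the mixture of cells was not tested as a cause. Among markers of other cells, the myeloid and dendritic list was called higher (camera adjusted p = 0.0140, and 0.255 with an estimated correlation). That call rests on 9 tested of 24 members, of which 3 rose and 0 fell. Over all libraries Lyz2 had 14 counts and Csf1r 6, while Cd68 had 5050 and was not called. The CD4 T cell list and the natural killer and gamma delta list were not called (camera adjusted p = 0.735 and 0.380).

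MYC and ribosome biogenesis genes were lower with DCA in experiment 1 and not in experiment 2 by camera with a preset correlation. With an estimated correlation the adjusted p was 0.256 in experiment 1 and 0.479 for the difference, which fry did not call either (0.150). Removal of a GC trend kept 88.0% of the median difference (88.5% to 113% with 1 mouse left out) and cyclic loess 80.9% (74.3% to 110%), which argues against either trend as the whole cause. The mean change of the list was -0.53 ± 0.31 in experiment 1 and -0.05 ± 0.23 in experiment 2 (SD, n = 3 mice each, exact two-sided p = 0.2, where the smallest possible is 0.1). Strain and batch coincide with experiment, so their parts cannot be told apart, and with 3 mice each the difference between mice could not have passed 0.05.

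The untreated cells of the experiments differed in 8131 genes, against a highest value of 0 in the other splits, which at 10 are too few for a share under 0.05. Among the 15148 genes with a GC content and a length, 95.4% of the calls were left in number after removal of a GC trend and 99.1% after removal of a length trend, so neither trend was the whole cause. A difference of strain, of peptide and of library batch stay open and cannot be told apart, since each coincides with experiment. The beta segments of the T cell receptor differed between the experiments: the lowest Trbv12-1 value among the libraries of experiment 1 was 169 CPM, and Trbv14 had 0 counts there. For the beta segments this is consistent with OT-1 cells in experiment 1, as the strain tags give, and not with the titles. The alpha segments matched for the same check did not add to this, all being at or below 5.09 CPM. Trav14D-1, Trav14D-2 and the Trav7D segments were not matched by name and were not examined. In experiments 1 and 2 the mean CPM was 2.71 and 4.01 for Trav14-1, 1.09 and 2.46 for Trav14-2, 1.95 and 1.16 for Trav14-3, and 0.108 and 1.09 for Trav14D-3.

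Other groupings of the libraries showed which counts chance can be excluded for. For DCA over both experiments 2638 genes were called, against a highest value of 148 in the other of 100 random splits of the 12 libraries and 1 in the other of 32 splits that part all 6 mice; in both sets 1 split, the real one, gave a value as large, and chance can be excluded. For lists with a preset correlation the real value was 11 and the highest other was 12. Of the 100 splits 4 gave a value as large, but they were drawn without regard to the pairing of libraries by mouse. Of the 32 splits that part all mice 4 gave a value as large, so chance cannot be excluded for this count. For lists with an estimated correlation the real value was 2 and the highest other 0 in both sets (1 as large). Chance can be excluded for this count, in fits without a term per mouse, but not from it for either list by itself. In the other splits the effect of DCA stays in the spread, which can lower their calls. With a term per mouse the p53 list was not called (camera adjusted p = 0.203 with an estimated correlation). Within experiment 1 the values were 2622 genes against 2 and 13 lists against 8, and within experiment 2 they were 717 genes against 2 and 6 lists against 5, each with 10 splits, too few for a share under 0.05. The arms of mice were also swapped, with each experiment's effect taken as the mean over its 3 mice of the differences in log2 CPM, in place of the fitted log2 fold changes that gave 0.265. On that measure the correlation between the experiments was 0.356 for the real arms. It was at most 0.235 in size for the others, over 16 swaps in all, with 1 as large, too few for a share under 0.05.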

How the results depend on the processing

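A minimum fold, removal of a GC trend, cyclic loess normalization and limma on log2 CPM with TMM were chosen after the results had been seen; the other settings were fixed earlier.

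The count for DCA against untreated over both experiments was 2638, and stayed within 1.5 times that under RLE, limma-voom, DESeq2, both filters, a term per mouse, GC removal, cyclic loess and limma on log2 CPM (2094 to 3456). It was 1558 with a minimum fold of 1.1 and 403 with an absolute log2 fold change of at least 1, both by construction, and 46 with no experiment term, which leaves the difference between experiments in the error. With an absolute log2 fold change of at least 1, 552 genes were left for DCA against untreated in experiment 1, 183 for DCA against untreated in experiment 2, 19 for the difference of the DCA effect between experiments and 4492 for experiment 2 against experiment 1 in untreated cells. With only the libraries of 1 experiment, 1251 and 1564 genes were called in experiments 1 and 2; the cause was not tested. The count in experiment 2 (717) was 1171 by limma-voom, 1512 by DESeq2 and 1116 with no filter. The count of the difference (52) was 458 by DESeq2, 566 with no filter, 24 with a term per mouse and 28 under cyclic loess (62 with the same limma test and TMM). The cause was not tested.

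With 1 library left out the counts were 210 to 629 in experiment 2 and 1 to 217 for the difference, so the number of genes that differ is not fixed by these libraries. Gene lists past the set test were 11 with a preset correlation and 9 to 12 under the other settings run with it and by fry. They were 2 with an estimated correlation, which allows for genes of a list moving together. With that and a term per mouse, proliferation was called (0.0202) and p53 was not (0.203). With that and 1 library left out, proliferation was called in 7 of 12 fits (adjusted p up to 0.109) and p53 in 11 of 12 (up to 0.0655). The agreement of the DCA effect between experiments (0.265) was 0.528 at a mean log2 CPM of at least 3, 0.454 with each experiment alone, 0.450 with a term per mouse in each, and 0.204 to 0.245 with 1 library left out. The cause was not tested.

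Of 123 results for single genes, 1 reversed: Ldha log2 fold change over both experiments was 0.0062 under cyclic loess (-0.17 with TMM by edgeR and by the same limma test), so the sign turned with the scaling and not with the test. Under cyclic loess 107 kept their direction and side of the threshold, 14 lost a call and 1 gained one, while the same limma test with TMM kept all 123. With a term per mouse 103 were the same and 10 lost a call, and with no experiment term 80 lost a call. RLE kept all 123. Calls changed with 1 library left out for genes with few counts, such as Ifng and Pdk2, and for abundant ones, such as Cd8a and Pdk3, and depth was not tested as a cause.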

Other observations

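All the gene lists in this part were chosen after the results had been seen, as were the genes named from them and the tests on them.

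Genes that fold, move and degrade proteins were lower with DCA over both experiments under TMM scaling. Of 31 proteasome genes, 26 fell and 0 rose (median -0.26), and of 20 chaperonin and HSP90 chaperone genes, 15 fell and 0 rose (-0.34), among them Cct7, a chaperonin subunit, at -0.55. Of 32 genes of glycosylation and entry into the endoplasmic reticulum, 23 fell and 0 rose (-0.30), including the chaperone gene Hspa5 (-0.52). Of 28 spliceosome genes, 17 fell and 0 rose (-0.25). Under cyclic loess these medians were -0.12, -0.18, -0.17 and -0.16, still lower by camera with a preset correlation. With an estimated correlation the adjusted p was 0.0911, 0.0961, 0.0617 and 0.0462 under TMM. Under cyclic loess it was 0.260, 0.266, 0.203 and 0.203, and none of the 4 was called. Of the 20 chaperone genes, 16 fell in experiment 1 (median -0.46) and 2 in experiment 2 (-0.20). By camera this difference was called (adjusted p = 0.00113), but not with an estimated correlation (0.573) or by fry (0.135). For the proteasome, glycosylation and spliceosome lists camera did not call a difference between experiments (0.237, 0.237 and 0.713).

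Genes of the actin cytoskeleton (15 of 24 fell, median -0.21), the T cell receptor complex (8 of 19 fell, -0.17) and MHC class I with peptide loading (7 of 20 fell, -0.11) had 0 rises. With an estimated correlation their adjusted p was 0.0462, 0.0911 and 0.0617. Under cyclic loess none of these 3 was called by camera (0.195, 0.465 and 0.642), with medians of -0.07, -0.04 and -0.00. With TMM the T cell receptor complex list was not called by camera in experiment 1 (0.123) and was in experiment 2 (1.65e-06). Its difference between experiments was not called (0.0501). Cytosolic ribosomal protein genes went both ways (7 rose and 8 fell of 51, median -0.00), and their median turned to 0.15 under cyclic loess. There 41 of 51 were above 0, and the list was called upward by camera with a preset correlation (6.85e-08) and not with an estimated one (0.266).

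The p53 pattern was tested on a second list of 17 p53 targets that shares no gene with the first. Of these 9 rose and 0 fell (median 0.55), including Cd80 (1.08), Dcxr (1.01) and Ercc5 (0.87). The adjusted p with an estimated correlation was 0.0462 over both experiments, 0.110 in experiment 1 and 0.00460 in experiment 2, and 0.0933 over both under cyclic loess. In experiment 1, 3 of the 17 rose (median 0.31), and in experiment 2, 8 rose (median 0.77), with 0 falls in each. The list had a higher effect in experiment 2 (median difference 0.44, camera adjusted p = 0.00324; 0.0368 by fry, 0.274 with an estimated correlation). A term per mouse was not tried on this list. A rise of p53 targets under DCA, larger by estimate in experiment 2, stays a hypothesis found and tested on the same libraries.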
